A study of Oryctolagus cuniculus with 6 samples.

How the data were processed

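Tracheal mucosa RNA was sequenced as 6 polyA libraries on a DNBSEQ-T7, per the labels' protocols, with 3 libraries in the high cuff pressure group and 3 in the control group. Samples were assigned to groups and numbered by their library names in the labels. Control replicate 3 carries the title S4 there and no sample the title S3, so the meaning of the replicate numbers is uncertain and whether a library was left out is not known. The labels place all libraries in a single batch. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.3b and edgeR, without a role or, for edgeR, a version; genome build, annotation release, strand setting and counting options are not given in the sources used here.

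The deposited gene table holds raw read counts per gene for 29587 genes and, per the file headers, FPKM values by the authors; each FPKM equals the count divided by a gene length and by the library total, so model lengths were derived from the ratio. A second deposited table adds the authors' log2 fold change, p-value and q-value per gene and the annotation of genes with Gene Ontology and KEGG terms. The deposited enrichment tables give the authors' rich factor, a ratio of shares, with p-values and q-values and numbers of genes. Of the genes, 13436 carry no symbol. Those among them that passed the count filter were tested but not named. Of the 13724 genes tested, 11139 carry a symbol. For 9 list genes the match was made through an older symbol or the row's description. The reference gene table for the species matched 0 of the gene identifiers, so names and positions come from the deposited table alone.

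Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the groups, which left 13724 genes; TMM factors were computed; and glmQLFit with robust estimation and glmQLFTest compared high cuff pressure with control, with Benjamini-Hochberg adjustment and a threshold of 0.05. A second count used a minimum fold of 2. CPM are TMM-normalised, log2 CPM use a prior count of 2, and standard errors are the log2 fold change divided by the square root of F. Total counts per library ranged from 10501734 to 14415754, so 3 counts, the floor used for a group at 0, correspond to 0.208 to 0.286 CPM in a single library. Folds against a group with 0 counts use that floor over the whole group; with 1 to 3 counts in a group the ratio of counts is given with an exact Poisson interval of 95%. Intervals and floors cover counting error only. Each library counted as 1 replicate because the labels state n = 3 per group. No pair within a group agreed within sampling noise (chi-square per degree of freedom 56.1 to 137), so none was treated as a repeated deposit of the same library; this does not show that the libraries came from separate animals.

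Before the data were examined, the design, 37 gene lists (18 for pathways and 19 for cell types), the alternatives and the rule for named genes were fixed. The rule names the 10 largest rises and 10 largest falls among genes with a symbol, adjusted p under 0.05, groups that do not overlap and at least 1 CPM in every library of the higher group. It adds 3 genes with the smallest p, in the direction most members moved, from each list with at least 3 members past the threshold or a camera adjusted p under 0.05. It further adds IL1B, IL6, CXCL8, TNF, PTGS2, HMOX1, VEGFA, MUC5AC, SCGB1A1, FOXJ1 and KRT5 where measured, and the 5 terms with the smallest p in each deposited enrichment table. Not every gene the rule gives is described in the text. Of 678 list entries, 537 had a row in the table. Lists were tested with camera in limma 3.58.1 on log2 CPM (preset correlation 0.01), with camera at an estimated correlation and fry beside it, and adjusted over the 35 lists with at least 2 tested members; the thyroid and red blood cell lists had 1 tested gene each, with log2 fold changes of -0.83 and -0.05. Annotation sets of 15 to 500 tested genes were tested in the same way; at most 5 per direction were named, skipping sets that shared over 50% of members with one already named.

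The alternatives were DESeq2 1.42.0, RLE factors, total counts only, no filter, at least 1 CPM in 3 libraries, limma-voom, a fit without robust estimation, the replicate number as a block, limma-trend on log2(FPKM + 1) for genes at 1 FPKM or more in 3 libraries, the same with a pseudocount of 0.1 or without a filter, and leaving out each library in turn. Added after seeing the data were a fit without mitochondrial genes, a fit with a smooth trend over gene length removed per library (lowess span 0.5), a fit without a pair of libraries that stood apart, and edgeR's exact test on genes with at least 2 counts.

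The tests were tested on simulated data for this comparison: counts were drawn from the real means, library sizes and spread, with known changes put in, in 3 draws that together changed 150 genes at each size. The quasi-likelihood test found 2.67% of genes changed 2-fold, 66.7% of those changed 4-fold, 92.7% of those changed 8-fold and 99.3% of those changed 16-fold. It made a mean of 10.7 false calls per draw among about 13607 genes. Few genes were changed and genes were drawn independently, so these rates need not carry over to the real comparison.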

Results

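Gene expression was profiled by polyA RNA-seq in the tracheal mucosa of New Zealand rabbits aged 3 months. In the injury model, a 3.0 mm tracheal tube lay 13 cm deep and its inflatable cuff was held at 35 cmH2O for 2 h. The 3 libraries of this high cuff pressure group were compared with 3 control libraries; the labels do not say how the controls were handled or when tissue was taken. The labels call the material epithelial cells, while their protocol names whole mucosa. Library totals ranged from 10501734 to 14415754 counts, and the group means of 12092600 and 11867800 counts differed by less than the spread between libraries (exact permutation test, two-sided p = 0.90). Each library is taken as 1 replicate, since the labels state n = 3 per group; p-values measure the spread between these libraries only.

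The comparison asks which transcripts differ in mucosa exposed to an over-inflated cuff. Transcripts higher with high cuff pressure included those of the neutrophil genes CSF3R, S100A8 and S100A12, the cytokines IL1A, IL1B, CSF3 and CXCL5, the matrix protease MMP10 and its inhibitor TIMP1, the wound keratin KRT16, and the mitotic genes AURKB, CCNB2 and MKI67. Transcripts of the proteoglycans OGN, ASPN, KERA and LUM, of the enzymes FMO2 and CYP2A10, and of the plasma cell joining chain JCHAIN were lower. Of 13724 genes tested, 503 were higher and 222 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 700 of these 725 differed at least 2-fold. In all 725 the 3 libraries of one group lay entirely above those of the other, which the test itself favours. Over all tested genes, 37.3% were separated in this way, where chance gives 10% for a single gene. Genes vary together, so the share for a single split can lie far from 10%, and no share is given for other splits.

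The 10 largest rises with a gene symbol were led by SERPINB2, a serine protease inhibitor of squamous epithelium. It had 4.93 ± 0.757 CPM (SD, n = 3) with high cuff pressure and 0 counts in the 3 controls, which makes it at least 67.3-fold higher against a floor of 3 counts over the group. MMP10, the protease stromelysin-2, had 1 count over the controls and a count ratio of 428 (95% counting interval 76.4 to 16971). FOSL1, an AP-1 transcription factor subunit, also had 1 control count and a ratio of 166 (29.3 to 6605). IL1A had 2 control counts and a ratio of 139 (38.0 to 1155). These ratios and the bound for SERPINB2 moved when 1 library was left out. That of MMP10 was 200.1 without high cuff pressure replicate 1 (35.2 to 7978) and 266 without control replicate 2, and without control replicate 3 it was at least 94.97-fold higher against 0 control counts. FOSL1 had a ratio of 110.4 without control replicate 3 and was at least 34.3-fold higher without control replicate 2. IL1A had ratios of 71.7 without high cuff pressure replicate 1, 86.2 without control replicate 2 and 92.4 without control replicate 3, and was at least 66.2-fold higher without control replicate 1. The bound for SERPINB2 was 41.5-fold without control replicate 2 and 44.5-fold without control replicate 3. Where the control left out held 0 counts of the gene, the value fell only because fewer control reads remained. This covers SERPINB2, MMP10 without control replicate 2, FOSL1 without control replicate 3, and IL1A without control replicate 2 or 3. CSF3R, the granulocyte colony-stimulating factor receptor, stood at 120 ± 104 CPM against 0.773 ± 0.337 CPM (log2 fold change 7.28 ± 0.84 SE, edgeR adjusted p = 0.016). S100A12 stood at 985 ± 550 against 7.76 ± 7.15 CPM and S100A8 at 352 ± 269 against 3.08 ± 1.94 CPM; both encode calcium-binding proteins abundant in neutrophils. The set was completed by IL1B (log2 fold change 6.64), the growth factor-binding protein FGFBP1 (6.48) and the chemerin-binding receptor CCRL2 (6.47), all with edgeR adjusted p of at most 0.030. Without high cuff pressure replicate 1 the log2 fold change was 6.33 for CSF3R, 6.08 for S100A8, 5.68 for IL1B and 5.84 for CCRL2. It was 7.94 for IL1B, 7.37 for FGFBP1 and 7.41 for CCRL2 without control replicate 1, and 8.01 for S100A12 without control replicate 3. S100A8 (chromosome 13, 39004122 to 39005042) and S100A12 (chromosome 13, 39017627 to 39018847) are neighbours, as are IL1A (chromosome 2, 97560400 to 97570279) and IL1B (chromosome 2, 97614349 to 97618581). Positions follow the deposited table, and its genome build is not given in the sources used here.

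The 10 largest falls included OGN, ASPN and KERA, which encode small leucine-rich proteoglycans of the connective tissue matrix. OGN fell from 157 ± 33.1 to 16.9 ± 8.89 CPM (log2 fold change -3.22 ± 0.46 SE, edgeR adjusted p = 0.018). ASPN (-3.92; chromosome 1, 70308335 to 70328717) lies near OGN (chromosome 1, 70251553 to 70270135), and KERA (-3.50) was at 0.930 ± 0.511 against 10.5 ± 2.30 CPM. SFRP2, a secreted Wnt modulator, fell from 131 ± 33.5 to 9.68 ± 6.50 CPM (log2 fold change -3.75, edgeR adjusted p = 0.023), and MYOC (-3.63) fell as well. FMO2, a flavin-containing monooxygenase of airway tissue, fell from 436 ± 128 to 55.0 ± 14.3 CPM (log2 fold change -2.99, edgeR adjusted p = 0.016). CYP2A10, a cytochrome P450, fell from 5436 ± 3233 to 311 ± 338 CPM (-4.13, adjusted p = 0.048). The counting options for reads shared with related CYP2A genes are not given, so its level is uncertain. The esterase gene AADAC (-3.87), the potassium channel subunit gene DPP6 (3 counts over the high cuff pressure group, count ratio 23.1, 95% counting interval 7.64 to 114, or a ratio of 40.5 without high cuff pressure replicate 3) and ERICH6B (-4.06) made up the rest. The AADAC row spans chromosome 14, 45753365 to 45921747, with a model length of 7956 bp, so it may cover other genes and its level is uncertain. AADAC stood at 2.11 ± 0.141 against 31.0 ± 34.7 CPM, and its log2 fold change was -2.38 without control replicate 2. That of MYOC was -2.87 without control replicate 1, that of ASPN -4.70 without high cuff pressure replicate 3 and that of CYP2A10 -5.55 without high cuff pressure replicate 2. ERICH6B had -5.45 without high cuff pressure replicate 1 and -3.44 without control replicate 2.

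**Figure D1:**
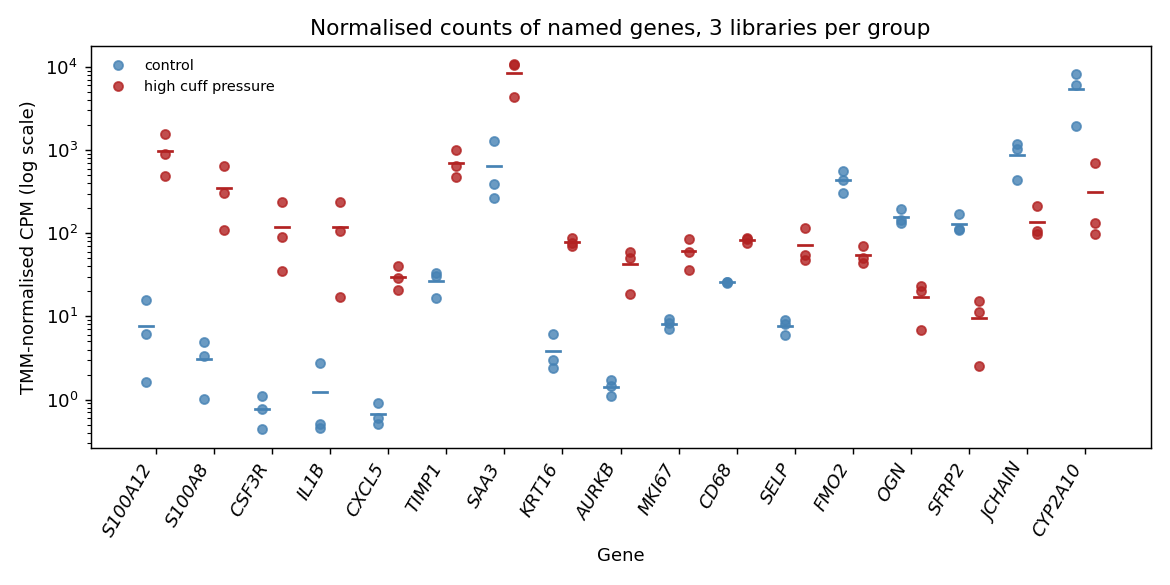
TMM-normalised CPM on a log axis for 17 named genes, with 1 point per library, a bar at the group mean, and 3 libraries per group in red (high cuff pressure) and blue (control). For each gene the points of the groups do not overlap; SAA3 reached a mean of 8505 CPM with high cuff pressure against 642 CPM in control.

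Among neutrophil markers, 7 of 14 tested genes rose and 0 fell, with a list median of 3.44 on the log2 scale; 12 rose when adjusted over the list alone. The neutrophil median was 2.70 without high cuff pressure replicate 1, 4.40 without high cuff pressure replicate 3 and 5.07 without control replicate 3. Each such fit filtered genes anew, so the tested members of a list may differ and its median may move for that reason too. Camera with a preset correlation called the list (adjusted p = 6.3e-09), also in all 6 fits with 1 library left out, but the adjusted p = 0.62 with an estimated correlation. Besides CSF3R, S100A8 and S100A12, these included the chemokine receptor CXCR1 (6.07) and the formyl peptide receptor FPR1 (5.80). Without control replicate 1 these were 6.76 and 6.46, and CXCR1 had 5.43 without high cuff pressure replicate 1. CXCR1, FPR1, CSF1R, MMP2 and the mitochondrial genes are named after their values were seen. Of 14 monocyte and macrophage markers, 4 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 1.44 and camera adjusted p = 0.0024 (adjusted p = 0.62 with an estimated correlation). They were CD68, at 83.1 ± 6.13 against 25.8 ± 0.362 CPM, CD14 (2.27), MARCO (3.85, or 4.61 without control replicate 1) and CSF1R (1.61). Of the 14 markers, 10 had positive and 4 negative values. The negative ones, named after their values were seen, were C1QA (-1.05), C1QB (-0.93), C1QC (-0.80) and CD86 (-0.43), and they did not pass.

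Of 16 cytokine and chemokine genes tested, 6 rose and 0 fell, and 9 rose and 1 fell when adjusted over the list alone (median 2.41, camera adjusted p = 0.00090, and adjusted p = 0.62 with an estimated correlation). CXCL5 (ENSOCUG00000011838, chromosome 15, 76297487 to 76298504), a neutrophil-attracting chemokine, had the smallest p of all genes tested: 30.0 ± 9.46 against 0.670 ± 0.205 CPM (log2 fold change 5.45 ± 0.41 SE, edgeR adjusted p = 0.011). CSF3 rose by 6.14 on the log2 scale (4.94 without high cuff pressure replicate 1, 7.01 without control replicate 1) and CXCL8 by 3.93 (3.26 without high cuff pressure replicate 1). The gene that fell when adjusted over the list alone was IL18, an interleukin-1 relative named after its value was seen, at 89.8 ± 15.5 against 179.6 ± 40.9 CPM. IL6, matched by the description of its row, had a log2 fold change of 4.35 ± 1.20 SE and did not pass (edgeR adjusted p = 0.070). IL6 had 3.37 without high cuff pressure replicate 1, 6.81 without control replicate 1 and 3.75 without control replicate 3, and it passed in none of these fits. PTGS2, the inducible cyclooxygenase, stood at 46.0 ± 36.8 against 58.2 ± 8.78 CPM and did not pass (edgeR adjusted p = 0.71); its log2 fold change of -0.34 was -1.16 without high cuff pressure replicate 1. TNF, MUC5AC and SCGB1A1 had no row with that symbol and were not analysed here.

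Matrix proteolysis was the list with the most members past the threshold after cell cycle: 10 of 19 tested genes rose and 1 fell (14 and 2 adjusted over the list alone; median 2.88, or 3.62 without control replicate 1). TIMP1, an inhibitor of matrix metalloproteinases, reached 705 ± 271 against 26.9 ± 9.06 CPM (log2 fold change 4.71, edgeR adjusted p = 0.013). PLAT, which encodes a protease that activates plasminogen, rose by 3.74, and the gelatinase gene MMP2 fell by 1.08 on the log2 scale. Camera gave an adjusted p = 1.4e-06, and the adjusted p = 0.44 with an estimated correlation. Of 11 wound keratin and squamous genes, 4 rose and 0 fell (7 and 0 adjusted over the list alone; median 1.23, also with SERPINB2 set to its bound). KRT16, a keratin of wounded epithelium, stood at 77.8 ± 9.09 against 3.86 ± 2.01 CPM and TGM1, a transglutaminase of the cornified envelope, rose by 3.48 (4.25 without control replicate 1). Levels of KRT16, SAA3 and the S100A genes are uncertain, since each has close relatives and the counting options for shared reads are not given. The KRT16 row spans chromosome 19, 42551334 to 42572960, and the related keratin KRT14 had no row. Camera gave an adjusted p = 1.6e-04 for this list, and the adjusted p = 0.44 with an estimated correlation. Among 11 antimicrobial and acute phase genes, PGLYRP1 (6.42, or 5.63 without high cuff pressure replicate 1), CHI3L1 (3.56) and SAA3 (3.73, or 4.70 without control replicate 1) rose and 0 fell (4 and 0 adjusted over the list alone; median 1.54, or 2.31 without control replicate 1). Camera gave an adjusted p = 0.011 (0.097 without high cuff pressure replicate 1), and the adjusted p = 0.63 with an estimated correlation.

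Of 20 cell cycle genes tested, 18 rose and 0 fell, and all 20 rose when adjusted over the list alone, with a median of 3.22. AURKB, a mitotic kinase, stood at 42.8 ± 21.3 against 1.43 ± 0.323 CPM (log2 fold change 4.89 ± 0.51 SE, edgeR adjusted p = 0.014). CCNB2, a mitotic cyclin, rose by 4.82 (4.20 without high cuff pressure replicate 3) and MKI67, the proliferation antigen Ki-67, from 8.17 ± 1.10 to 60.5 ± 24.7 CPM. The 2 genes that did not pass over all genes were MCM4 (2.30) and PCNA (1.47), named after their values were seen. Both passed without high cuff pressure replicate 1 (edgeR adjusted p = 0.017 and 0.010), and MCM4 had 1.52 without high cuff pressure replicate 3. Camera gave an adjusted p = 1.6e-15, and the adjusted p = 0.62 with an estimated correlation. With a median of 0.24, the regulated cell death list had 2 of 19 tested genes higher and 0 lower (2 and 0 adjusted over the list alone). They were NLRP3 (2.74), an inflammasome sensor, and BAK1 (1.23), a pro-apoptotic BCL2 relative; BAX had 0.89 and did not pass, though it did without high cuff pressure replicate 1 (edgeR adjusted p = 0.035). Camera gave an adjusted p = 0.046 for regulated cell death (0.24 without high cuff pressure replicate 1 and 0.061 without control replicate 1), and the adjusted p = 0.62 with an estimated correlation. The median of this list was -0.16 with total-count scaling.

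The called lists for tissue cell types had medians from -0.99 to 0.80. Among 11 endothelial genes, SELP, an adhesion receptor for leukocytes, rose from 7.69 ± 1.57 to 72.6 ± 36.8 CPM and PECAM1 by 1.53, while TIE1 had 0.98 and did not pass, except when high cuff pressure replicate 1 was left out (edgeR adjusted p = 0.041). The endothelium list had 2 higher and 0 lower both over all genes and adjusted over the list alone (median 0.80, camera adjusted p = 0.041, and adjusted p = 0.78 with an estimated correlation). Its camera adjusted p was 0.082 without high cuff pressure replicate 2, 0.12 without high cuff pressure replicate 3 and 0.065 without control replicate 3. Among 9 B and plasma cell genes, JCHAIN (-2.67) and MZB1 (-1.62) fell and 0 rose (4 fell and 0 rose adjusted over the list alone); TNFRSF17 had -1.56 and did not pass, except when high cuff pressure replicate 1 was left out (edgeR adjusted p = 0.042). The median was -0.99 (camera adjusted p = 0.0072, and adjusted p = 0.62 with an estimated correlation). Among 11 genes of fibroblasts, OGN and LUM (-1.86) fell, MFAP4 had -1.57 without passing, and 0 rose, also adjusted over the list alone (median -0.76, camera adjusted p = 0.037, and adjusted p = 0.78 with an estimated correlation). Its camera adjusted p was 0.24 without high cuff pressure replicate 1, 0.061 without control replicate 1 and 0.091 with total counts only, and its median was -1.48 without high cuff pressure replicate 3. Of 8 smooth muscle genes, 0 passed with edgeR over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and 0 were lower with DESeq2. Their median was -0.97 (camera adjusted p = 0.046, and adjusted p = 0.78 with an estimated correlation). The camera adjusted p was 0.32 without high cuff pressure replicate 1, 0.057 without control replicate 1, 0.067 without control replicate 2 and 0.16 with total counts only. Over 20 settings beside the main fit, camera called smooth muscle in 11. The call was also lost with the length trend removed, in the FPKM settings and without the pair of libraries that stood apart. The values of LMOD1, MYH11 and SYNPO2 were -1.18, -1.28 and -1.54. Without high cuff pressure replicate 3 the median of smooth muscle was -1.60, MYH11 had -2.03 and SYNPO2 had -2.86 and passed (edgeR adjusted p = 0.027). This median was -0.45 and MYH11 had -0.75 without high cuff pressure replicate 1. The smooth muscle mean was 4.99 log2 CPM in high cuff pressure replicate 1 and 7.71 to 9.03 in the other 5 libraries. Of 18 genes of multiciliated cells, 0 passed with edgeR over all genes (5 had an unadjusted p under 0.05, and 4 were lower with DESeq2). Adjusted over the list alone, 3 were lower: CCDC39 (-2.11), DNAH5 (-2.05) and CFAP43 (-1.79). Without high cuff pressure replicate 1 these had -2.92, -2.67 and -2.40 and passed over all genes (edgeR adjusted p = 0.010, 0.018 and 0.015). Their list median was -0.41 (camera adjusted p = 0.014, and adjusted p = 0.78 with an estimated correlation), and without high cuff pressure replicate 3 it was -0.06 (camera adjusted p = 0.38). FOXJ1, the regulator of multiciliated cells, stood at 293 ± 100 against 322 ± 65.3 CPM (edgeR adjusted p = 0.81).

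Of the 35 lists with at least 2 tested genes, camera called 9 higher and 4 lower with the preset correlation, and 0 passed with an estimated one. Regulated cell death failed there although its estimated correlation of 0.0079 lay below the preset 0.01, so correlation alone did not remove that call. With 6 libraries the estimated setting has few degrees of freedom and little power. Failing it therefore does not tell real from false calls. The other 22 were not called, among them basal cells, club and goblet cells, interferon response, immediate early genes, hypoxia and glycolysis, and oxidative stress response. KRT5, the basal cell keratin, stood at 1235 ± 1024 against 237 ± 103 CPM and did not pass (edgeR adjusted p = 0.073). Its log2 fold change of 2.38 was 2.81 without high cuff pressure replicate 1, where it passed (edgeR adjusted p = 0.020), and 1.50 without high cuff pressure replicate 3. The KRT5 row spans chromosome 4, 36508086 to 36751484, and the related keratins KRT6A and KRT6B had no row, so the level of KRT5 is uncertain. Within the hypoxia and glycolysis list, LDHA (2.85), ADM (3.07) and ENO1 (1.12) rose (LDHA 3.51 and ADM 3.98 without control replicate 1), while VEGFA had -0.10 (edgeR adjusted p = 0.82). The hypoxia and glycolysis median was 0.43 (camera adjusted p = 0.075; 0.043 without high cuff pressure replicate 2 and 0.035 without high cuff pressure replicate 3). The immediate early genes had a median of -1.27, which was 0.97 and called by camera without control replicate 1 (adjusted p = 0.0026). The interferon response was called without control replicate 3 (camera adjusted p = 0.040), and club and goblet cells without high cuff pressure replicate 2 (0.034) or control replicate 3 (0.049). Skeletal muscle had a median of -0.37, with 5 of the 12 genes that had a row tested in the main fit. The median lay between -1.45 and -2.22 when any high cuff pressure library or control replicate 3 was left out. The tested members may differ in these fits, so the moves cannot be put down to the removed library alone. Camera called the skeletal muscle list without high cuff pressure replicate 2, high cuff pressure replicate 3 or control replicate 3 (adjusted p = 0.035, 0.035 and 0.00081, with a median of -2.15 in the last). Camera also called airway ion and water transport without high cuff pressure replicate 1 or control replicate 3 (adjusted p = 0.0496 and 0.044) and T and NK cells without high cuff pressure replicate 3 or control replicate 2 (0.036 and 0.022). NF-kB response was called without high cuff pressure replicate 3 (0.035) and fibrillar matrix and TGF-beta without high cuff pressure replicate 1 (0.017). Calls gained in this way were not tested with an estimated correlation. HMOX1, a heme-degrading stress enzyme, had 0.46 (edgeR adjusted p = 0.29).

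**Figure D2:**
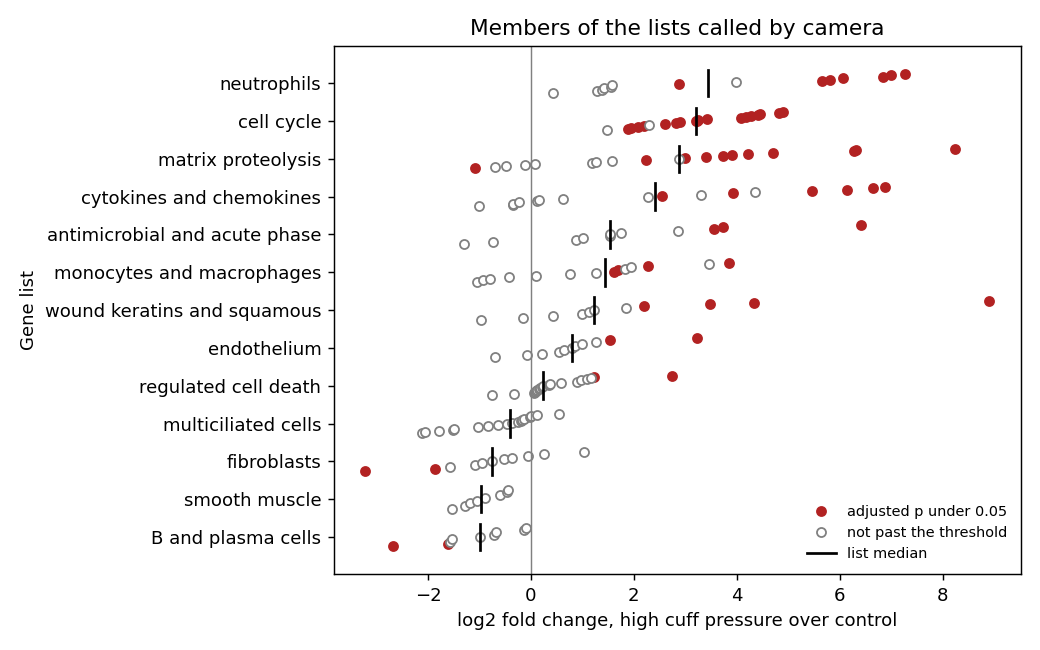
Log2 fold change of high cuff pressure over control for each tested member of the 13 lists called by camera; filled red points passed the adjusted p threshold of 0.05 and the vertical line marks the list median. Medians ran from 3.44 for neutrophils to -0.99 for B and plasma cells.

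Genes encoded in the mitochondrial genome took 28.8 ± 1.51% (SD, n = 3) of counts with high cuff pressure and 8.06 ± 3.17% in control (exact permutation test, two-sided p = 0.10, the smallest this design allows). The shares were 30.5% (Wilson 95% interval 30.5 to 30.6), 27.8% (27.8 to 27.8) and 28.1% (28.1 to 28.1) in the high cuff pressure libraries. In the controls they were 11.5% (11.5 to 11.5), 5.28% (5.27 to 5.30) and 7.38% (7.37 to 7.40). Of 13 mitochondrial mRNAs, 5 rose, led by COX1 (2.45), COX3 (2.35) and CYTB (2.35), subunits of the respiratory chain; the other 8 had edgeR adjusted p of up to 0.062 and the median of the 13 was 2.06. With high cuff pressure replicate 1 left out, 11 passed with edgeR. The calls were lost when any other library was left out, while the median stayed between 1.71 and 2.60 and all 13 had positive values. Levels of ATP8 and ATP6, which overlap, are uncertain. The 18 nuclear oxidative phosphorylation genes had a median of 0.24 and 0 passed with edgeR (1 had an unadjusted p under 0.05, and 0 rose with DESeq2). Camera gave this list an adjusted p = 0.073, and 0.012 with a median of 0.39 without high cuff pressure replicate 1. With mitochondrial genes left out, 500 genes were higher and 217 lower, of which 492 and 213 were also called with them.

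**Figure D3:**
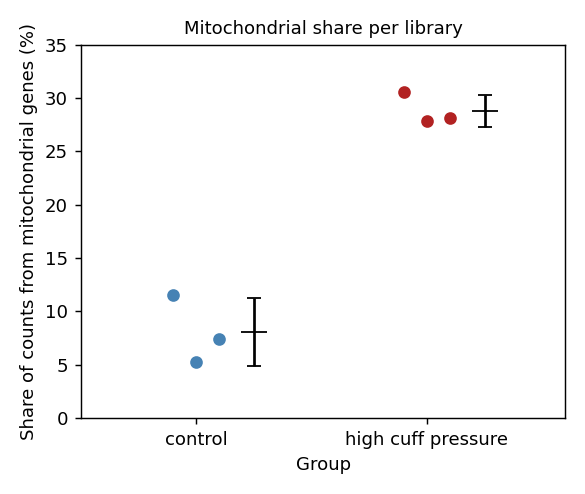
Share of all counts from mitochondrial genes, in percent, for each library by group, with the mean and SD (n = 3) in black. The 3 high cuff pressure libraries lie between 27.8% and 30.5% and the 3 controls between 5.28% and 11.5%.

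Of 3410 annotation sets built from the deposited gene annotation, camera called 37 higher and 14 lower with the preset correlation, and 0 passed with an estimated one. Structural constituents of the ribosome (200 genes, median 0.61, adjusted p = 2.4e-07), the respiratory chain (46 genes, median 0.48, adjusted p = 5.6e-04), DNA replication initiation (16 genes, median 2.14, adjusted p = 6.2e-04) and centromeric regions of condensed chromosomes (28 genes, median 1.18, adjusted p = 8.0e-04) were higher, as was the centromeric region of chromosomes (107 genes, median 0.40, adjusted p = 0.0025). Lower were cilium morphogenesis (163 genes, median -0.43, adjusted p = 5.6e-04), cilium (253 genes, median -0.41, adjusted p = 0.0046), monooxygenase activity (57 genes, median -0.74, adjusted p = 0.016) and limb morphogenesis (94 genes, median -0.40, adjusted p = 0.036). For each of these 9 sets the adjusted p = 0.99 with an estimated correlation, a setting with little power here, as for the lists. The respiratory chain set held 11 mitochondrial genes, and with the mitochondrial genes left out its adjusted p was 0.17. With a trend over gene length removed, the medians were 0.44 for structural constituents of the ribosome and -0.37 for cilium morphogenesis, and the adjusted p of monooxygenase activity and limb morphogenesis were 0.051 and 0.10. Limb morphogenesis had an adjusted p of 0.099 without high cuff pressure replicate 1, 0.11 without high cuff pressure replicate 2 and 0.16 without control replicate 2. Cilium morphogenesis and cilium had adjusted p of 0.0504 and 0.091 without high cuff pressure replicate 3 and were not called there.

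In the authors' deposited table, 754 genes were marked higher and 697 lower, of which 649 and 652 were tested here. In the same direction, 396 and 220 passed here, and 0 passed in the opposite one. Both comparisons use the same 6 libraries, so this is no separate evidence. The 5 Gene Ontology terms with the smallest p in the authors' deposited table were mitotic cell cycle process (66 genes higher, 28 lower), mitotic cell cycle, cell cycle, mitotic nuclear division and chromosome segregation. The 5 KEGG pathways there were Cell cycle (22 higher, 5 lower), Malaria (10 and 2), Fanconi anemia pathway (8 and 4), DNA replication (8 and 0) and Phagosome (15 and 5).

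The number of genes changed depended on which libraries were included and on the scaling: edgeR called 4 genes without high cuff pressure replicate 2, 76 without control replicate 1, 302 without high cuff pressure replicate 3 and 2623 without high cuff pressure replicate 1, and 0 without control replicate 2 or control replicate 3 (2691 and 2496 genes at an unadjusted p under 0.05; no other test of single genes was run on them). With total counts in place of TMM the median of all genes moved from -0.01 to -0.40 and the calls to 389 higher and 1241 lower. Folds of some genes stayed close over the 6 fits with 1 library left out, with CXCL5 at 5.20 to 5.74 and TIMP1 at 4.38 to 4.94, while 24 of the 47 named genes that passed moved over 1.5-fold in at least 1 of them.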

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

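The settings that added a fit without mitochondrial genes, without a length trend or without a pair of libraries, edgeR's exact test, and the annotation sets under settings other than camera's correlation were chosen after the data were seen. Against 725 genes changed (503 higher, 222 lower; 700 at least 2-fold), DESeq2 gave 2631 (1461 and 1170; 1959), edgeR's exact test 1968 (1145 and 823; 1773) and total counts only 1630 (1241 lower; 1499). Limma-trend gave 2182 with log2(FPKM + 1) (1748 lower; 1747), 1851 with log2(FPKM + 0.1) (1448 lower; 1644) and 341 without a filter (127 higher; 288). Without high cuff pressure replicate 1 (low smooth muscle markers) and control replicate 1 (high immediate early genes), 1595 genes were called (811 and 784; 1595). The cause of these differences was not tested; total counts only changes the scaling alone, while the FPKM settings also change the test and the filter. Leaving out 1 library gave 0 to 2623 genes (0 to 1362 higher, 0 to 1261 lower; 0 to 2320 at least 2-fold), with fewer samples in each fit; of the 47 named genes that passed, 0 did so without control replicate 2 or 3, 2 without high cuff pressure replicate 2, 16 without control replicate 1, 33 without high cuff pressure replicate 3 and 47 without high cuff pressure replicate 1. RLE factors, the other filters, limma-voom, the fit without robust estimation, the fit without mitochondrial genes and the length correction gave counts of genes changed within 1.5 times. No named gene that passed changed direction in any setting, and 24 of the 47 moved over 1.5-fold in at least 1 of the leave-one-out fits.

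The replicate numbers gave no sign of pairing: same-numbered libraries had correlations of -0.28, -0.20 and -0.23, and no library correlated best with its own number. These describe what is left once group means are removed, not expression levels, which correlated at 0.90 to 0.96 between libraries of a group. With 3 libraries per group few pairings are possible, so the values cannot show whether the numbers pair animals. With the replicate block, 244 genes were called (198 and 46), 244 of them at least 2-fold, and 79 annotation sets.

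Against 13 lists called, 4 passed fry (matrix proteolysis, wound keratins, cell cycle and neutrophils). With an estimated correlation, which leaves camera little power with 6 libraries, 0 passed. Under leave-one-out, cell cycle, neutrophils, matrix proteolysis, wound keratins, cytokines, monocytes and macrophages, and B and plasma cells passed camera in all 6 fits. The regulated cell death median turned to -0.16 with total counts only, -0.11 with log2(FPKM + 1) and -0.20 with log2(FPKM + 0.1). The immediate early list, not called, had a median of -1.27, which turned to 0.89 without the pair of libraries (camera adjusted p = 0.032) and ranged from -1.70 to 0.97 when 1 library was left out, the highest without control replicate 1, where camera called it higher (adjusted p = 0.0026). Against 51 annotation sets, 79 were called without a filter, 122 with unfiltered FPKM, 27 with the length trend removed, 0 with an estimated correlation and 35 to 88 when 1 library was left out. At this depth and spread, simulated 2-fold changes were found in 2.67% of cases, so changes of that size may be missed. The simulation changed few genes and drew genes independently, so this share need not hold for the real comparison, where 725 genes passed.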

Other observations

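The genes of the first paragraph, and the tests of nuclear respiratory chain genes, of epithelial share and of neutrophil transcripts, were chosen after the result was seen; the test of epithelial share took its present form after a first form had been read. Genes grouped here as clock output, a loose label since some, such as PER1 and PER2, belong to the circadian oscillator itself, included 2 that fell. These were NR1D2, from 168 ± 34.8 to 39.1 ± 10.7 CPM (edgeR log2 fold change -2.11, adjusted p = 0.017), and TEF (-1.37, adjusted p = 0.049). Of 10 genes in this group, 7 were tested, and all 7 had negative values, with a median of -1.37. HLF had -1.69, CIART -1.39, NR1D1 -1.30, PER1 -0.60 and PER2 -0.56 without passing. The 5 other clock genes tested did not pass and had mixed signs: ARNTL -0.77, CRY1 -0.41, CLOCK 0.09, NPAS2 0.30 and NFIL3 0.94. Genes were sorted into these groups after their values were seen. Neither the shared sign of the first group nor the difference in signs between the groups is therefore a separate result. Of 10 small leucine-rich proteoglycan genes tested, 4 fell (ASPN, KERA, OGN and LUM) and 9 had negative values, with a median of -1.82, while BGN had 0.02.

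The 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 725 genes and the highest other split 1; for genes changed at least 2-fold these were 700 and 1, and in each case 1 split, the real one, reached the count. For camera, 5 of the 10 splits called at least the 13 lists of the real one (highest other, 16), and 8 called at least its 51 annotation sets (highest other, 684, for high cuff pressure replicates 1 and 2 with control replicate 3). Each other split mixes libraries of both groups, so any group difference widens the spread within its sides and few single genes can pass. Part of the group difference also stays in the comparison. None of these counts is therefore a rate of false calls.

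Mitochondrial mRNAs were higher with high cuff pressure, with a median log2 fold change of 2.06. A length trend between libraries (Spearman correlation of fold change with gene length, across genes, -0.17) is argued against as the whole cause, since the median was 1.95 with the trend removed. A matching rise of nuclear respiratory chain genes is argued against as well: their median was 0.24 and their upper quartile 0.50, against 2.06 for the mitochondrial mRNAs. RNA quality was not measured in these tables, and RNA breakdown or cell damage that spares mitochondrial transcripts may contribute, as may the injury itself; neither was tested.

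Camera called the set of ribosomal protein genes, which are short, higher and that of cilium morphogenesis genes, which are longer, lower; 3 of 200 and 3 of 163 members passed singly, and both sets had an adjusted p = 0.99 with an estimated correlation. With the length trend removed the ribosomal median moved from 0.61 to 0.44 and the cilium morphogenesis median from -0.43 to -0.37, and camera adjusted p were 0.0011 and 0.0036, so the trend does not account for all of either value. For the cilium genes, a lower share of epithelium, fewer multiciliated cells within it and a change inside those cells cannot be told apart. The epithelial junction list was not called (median -0.27, camera adjusted p = 0.54), with 4 members positive and 15 negative. A first test, on list quartiles, argued against a lower share (basal lower quartile 0.07, multiciliated upper quartile -0.14), and was replaced by 1 per library because the libraries of the groups overlapped. The basal minus multiciliated list mean was 1.51 log2 units higher with high cuff pressure, but high cuff pressure replicate 1 (-1.81) lay within the control range and replicate 3 (1.31) stood apart. The multiciliated list was not called without that replicate 3.

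Cell cycle genes rose with a list median of 3.22. Length and scaling are argued against as the cause, since the median was 3.28 with the length trend removed and 2.83 with total counts only. Whether the transcripts came with arriving cells or rose in resident cells was not settled. In 3 of 3 pairs of high cuff pressure libraries the neutrophil and cell cycle means differed in opposite directions. Cell cycle means were 4.70, 5.55 and 6.52 log2 CPM in replicates 1 to 3, and neutrophil means 5.52, 4.72 and 3.88. Among these libraries the cell cycle genes thus did not follow the neutrophil markers. The test was written to need more than 3 libraries, so it could not have decided against neutrophils. Other arriving cells, such as monocytes, were not tested.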
